A study of Homo sapiens with 60 samples.

How the data were processed

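The data are 60 libraries of 3'-end RNA sequencing from spheroids of the colorectal cancer line HCT116. Per the labels' protocols, spheroids grew in high-glucose DMEM with 10% fetal bovine serum and 1% each of penicillin-streptomycin and non-essential amino acids, and were exposed from day 1 to day 8. RNA was extracted with RNeasy columns, 48 ng entered QuantSeq 3' FWD libraries with unique molecular identifiers, and these were amplified for 18 PCR cycles. The molecule field of the labels reads cytoplasmic RNA, and no fractionation step is given in the sources used here. Because QuantSeq reads the end of each transcript, 1 count stands for about 1 molecule and a gene's count does not grow with its length. Reads from internal runs of adenine, including those in introns of unspliced RNA, may also be primed and counted.

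The table used here holds estimated counts per gene as deposited by the authors, for 29744 genes in 60 columns. Per the submitters' processing notes, FastQC 0.11.9, UMI-tools 1.1.2, cutadapt 3.4, STAR and Salmon 1.5.2 were used with the GRCh38 genome, which gives neither the order nor the settings of these tools. How reads that match several genes were shared out, and which gene annotation was used, are not given in the sources used here, so genes with near-identical copies are reported as uncertain. The deposited estimated counts were not whole in 21.4% of values and were rounded to whole numbers here before any test. Coordinates were taken from a RefSeq annotation of GRCh38 by gene symbol. Of 11298 tested genes, 10328 matched by symbol, 803 by an older symbol and 167 not at all, and 61 names in the table carry a suffix that marks a copy.

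Groups were taken from the sample titles, which also label the 5 samples of each group as biological replicates. The columns of the table are named by group and plate well without a replicate number, so libraries are named by well and could not be paired across groups. Another characteristic in the labels gives the same untreated, nutrient-rich entry for all 60 samples and was not used. Nothing used here says whether replicates came from separate cultures or days, so p-values measure the spread between these samples. No pair of libraries of a group was identical or within sampling noise of another, and each was counted as 1 replicate.

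Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM. One quasi-likelihood negative binomial model was fitted with edgeR 4.0.16 in R 4.3.3 to all 60 libraries with a mean for each of the 12 groups, which left 48 residual degrees of freedom and gave a common dispersion of 0.0316. From it came 21 contrasts with two-sided F-tests: Medium 2 against Medium 1 without treatment and averaged over treatments, each of 5 exposures against untreated spheroids in each medium, the difference of each response between media, the departure of the combination from the sum of its parts in each medium, and kynurenic acid against kynurenine in each medium. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a contrast, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F, and 95% intervals use the model's degrees of freedom. CPM values are means ± SD over 5 libraries with TMM scaling.

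A total of 29 gene lists was fixed before the data were examined, along with the groups, the contrasts, the alternatives and the rule for named genes. Lists with at least 5 measured members, 27 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, and fry was run beside them. Camera compares a list with the other genes, and fry asks whether its genes move one way on balance. Counts of members that passed are given over all genes tested and adjusted over the list alone.

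The rule for named genes was as follows. In a contrast with more than 24 genes past the threshold, the 12 largest rises and the 12 largest falls were taken among genes that passed, had a mean of at least 10 CPM in the higher group and a symbol not based on a clone, and whose libraries did not overlap between the compared groups, a condition left out for contrasts of more than 2 groups. With 24 or fewer, up to 6 per direction were taken by p. The 3 members with the smallest p of each list past camera followed, and then genes named in advance whatever their result: ASNS, DDIT3, DDIT4, TXNIP, SESN2, HMGCS1, MYC and EGR1 between media, HMOX1, FTH1, TFRC and ALAS1 with hemin, CYP1A1, CYP1B1, TIPARP and AHRR with kynurenine or kynurenic acid, and CDKN1A and KRT20 with butyrate. In contrasts other than with untreated spheroids, those of them that did not pass are not all printed. Some other genes that the rule names are not reported here. Up to 30 genes per contrast were to be named in that order. That limit was exceeded after values were seen. Between untreated media, the genes beyond it that the rule lists were members of lists (EGR1, JUN, JUNB, CCNG2, CDKN1B, KLHL24, TIPARP, CYP1B1, CDKN1A, MT2A, MCM2, RRM2, CDC6, RPLP0, RPL39, ATP5G3, XBP1, GDF15, BTG2, MDM2, BIRC3, IER3, NFKBIA, IFIT1, IFIT2 and IFIT3) and genes named in advance (ASNS, SESN2, HMGCS1 and MYC). With the combination in Medium 2 they were IFIT3, SOX4, RRM2, HSP90AA1, TIPARP, HMOX1, CYP1B1, FTH1, TFRC, ALAS1 and AHRR, and with kynurenic acid in Medium 2 TIPARP and AHRR. Outside the rule, and chosen after their values were seen, are ATF3, HSPA5, SDF2L1, DDX58, BBC3, VEGFA, KDM4B, TNFAIP3, NFKBIZ, PKM, PFKFB4, RNF43, AXIN2, CENPE, CENPF, MKI67 and AADAT between untreated media. TXNIP is listed with 0 counts in the table and KRT20 with 180 over all libraries, so neither was tested.

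The steps were tested on counts simulated at the real library sizes for kynurenine against no treatment in Medium 1, with 200 changed genes among 11130. Of genes changed 1.5-fold, 24 of 67 (35.8%) were recovered, of those changed 2-fold 56 of 67 (83.6%) and of those changed 4-fold 66 of 66 (100%), with 5 false calls and 0 calls by the same edgeR model in a comparison without changes. A planted list was found by camera (adjusted p = 2.29e-72), and 0 of 27 other lists passed. With 5 libraries per group at the real totals, changes of 1.5-fold were thus mostly not recovered in these simulations. Recovery was not split by expression level.

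Library totals, detected genes and ribosomal RNA shares were compared between groups by exact two-sided permutation tests over all assignments of 5 against 5 libraries, adjusted over 11 comparisons per measure. Alternatives planned in advance were DESeq2 1.42.0, RLE scaling, no filter on low counts, a fit of the compared groups only, and leaving out each library in turn. Chosen after the data were seen were a term for the plate row, leaving out ribosomal RNA, thinning all libraries to 1346135 counts, and leaving out the 2 libraries that stood apart from their groups. A term for replicate numbers was planned and could not be fitted, since the columns carry none. Chance was gauged by refitting each contrast under 100 assignments of the same libraries, the real one included. Correlations of responses that share untreated libraries were set against 100 simulations without effects.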

Results

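RNA was measured in spheroids of HCT116, a human colorectal cancer cell line, that had grown with compounds linked to red meat intake or gut bacteria. The 60 libraries form 12 groups of 5, from 6 treatments in each of 2 media that the labels call Medium 1 and Medium 2. The treatments were none, butyrate at 1 µM, hemin at 0.1 µM, kynurenine at 1 µM, kynurenic acid at 1 µM, and hemin together with kynurenine, given from day 1 to day 8. Butyrate is a short-chain fatty acid made by gut bacteria, hemin is the iron-containing ring of haemoglobin in its oxidised form, and kynurenine and kynurenic acid are breakdown products of tryptophan. The series design states that spheroids were sampled either directly or after 3 h in nutrient-deprived medium, but no label used here says which of these Medium 1 or Medium 2 is, so the media are named here as the labels name them.

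Each library is a 3'-end count of transcripts with unique molecular identifiers. Totals ran from 1346135 to 3083231 counts per library with a median of 1901981, and 11298 of 29744 genes passed the filter on low counts and held 99.62% of all counts. The first principal component, which held 16.9% of the variance, followed the medium. Scores on it ran from -14.9 to -6.7 in untreated Medium 1 and from 14.9 to 28.1 in untreated Medium 2. With treatments included, Medium 1 scores lay between -42.6 and -0.1 and Medium 2 scores between 6.8 and 29.6, apart from 1 kynurenine library of Medium 2 (well A7) at -13.5. The median correlation of log2 CPM, counts scaled to a common library size, was 0.96 within groups, 0.9589 between groups of the same medium and 0.9469 between media. No pair of libraries in a group differed by as little as sampling noise, with chi-square values per degree of freedom from 2.77 to 33.9. In 2 libraries the distance from the group mean stood apart, 1 of butyrate in Medium 1 (well B2) and 1 of kynurenine in Medium 2 (well A7). The mean log2 CPM of the 416 genes lower in untreated Medium 2 was between 4.135 and 4.244 in all 5 kynurenine libraries of Medium 2, that of well A7 included, and between 4.905 and 4.986 in those of Medium 1.

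**Figure D1:**
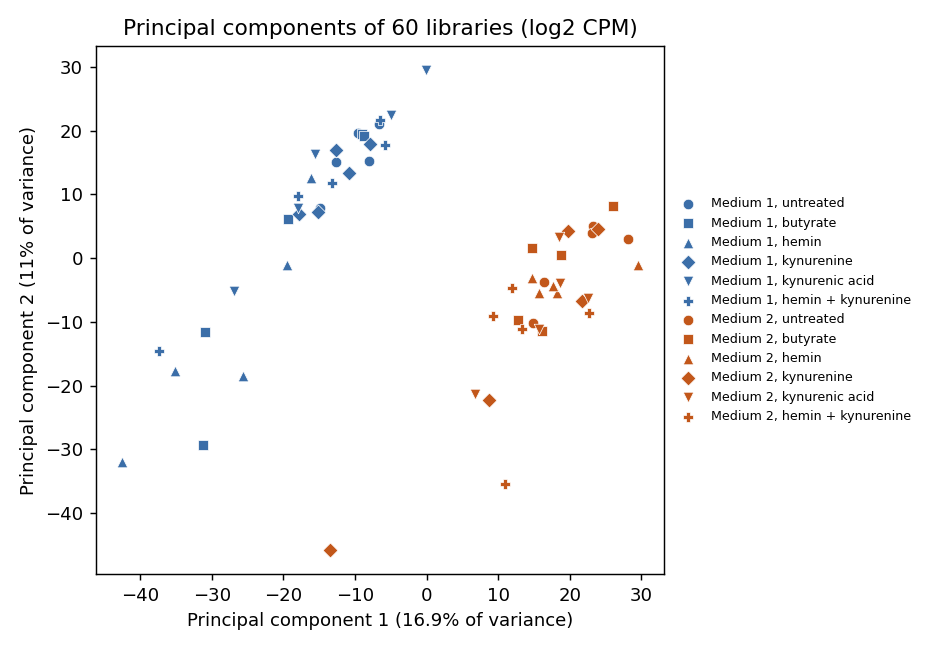
Each point is 1 of the 60 libraries placed by its scores on the first component (x axis, 16.9% of variance) and second component (y axis, 11% of variance) of log2 CPM, with colour for the medium and marker shape for the treatment. All 30 libraries of Medium 1 lie below 0 on the x axis and 29 of 30 of Medium 2 above it, the exception being a kynurenine library at -13.5.

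The first comparison asked how untreated spheroids of the 2 media differed, with 5 libraries each. Spheroids in Medium 2 had more RNA of DDIT4, an inhibitor of mTORC1 signalling, at 461 ± 102 CPM against 48.5 ± 9.61 (SD, n = 5), a log2 fold change of 3.25 (SE 0.25, adjusted p = 5.69e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gives every adjusted p of a single gene here). ANKRD37, a target of hypoxia-inducible factors, rose by 3.53 (SE 0.30, adjusted p = 1.77e-13), from 15 ± 3.89 to 176 ± 34.5 CPM. HERPUD1, which takes part in the degradation of misfolded proteins at the endoplasmic reticulum, rose by 2.32 (SE 0.16, adjusted p = 6.51e-17), from 122 ± 17.4 to 609 ± 60.1 CPM. The nuclear long noncoding RNA NEAT1, which holds paraspeckles together, moved the other way with a log2 fold change of -2.58 (SE 0.30, adjusted p = 4.26e-09), from 44.2 ± 10.3 to 7.35 ± 2.62 CPM. In all, 304 genes were higher and 416 lower in Medium 2 of the 11298 tested, and 550 and 585 with only these 2 groups fitted.

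Among the other genes with large rises were CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, with a log2 fold change of 2.83 (SE 0.33, adjusted p = 3.37e-09), and ADM, which encodes the peptide adrenomedullin, with 2.80 (SE 0.34, adjusted p = 1.9e-08). The lipase inhibitor ANGPTL4 rose by 2.56, the glutathione-degrading enzyme CHAC1 by 2.51, the endoplasmic reticulum chaperone DNAJB9 by 2.25, the transcription factor BHLHE40 by 2.05, the lipid droplet gene HILPDA by 1.97, the glycoprotein gene STC2 by 1.95 and the growth factor signalling inhibitor SPRY2 by 1.90. Among the genes with large falls, the laminin chain LAMA5 fell by 2.24 (SE 0.24, adjusted p = 1.18e-10), the Ras inhibitor NF1 by 2.45, the collagen gene COL27A1 by 2.49, the TGF-beta signalling inhibitor SMAD7 by 2.36, PABPC1L by 3.00 and LINC00342 by 2.67. AGAP4, GOLGA6L9, NPIPA5, PILRB and the readthrough STAG3L5P-PVRIG2P-PILRB had log2 fold changes of -3.44, -2.49, -2.38, -2.91 and -2.25, and these values are uncertain because such genes share sequence with close copies or overlap a neighbour. The call of NPIPA5 was lost without any 1 of the untreated libraries in wells E1, B5 and C5, with adjusted p-values from 0.0505 to 0.0741. DDIT4 lies on chromosome 10 at 72273924 to 72276036, HERPUD1 on chromosome 16 at 56932142 to 56944864, NEAT1 on chromosome 11 at 65422798 to 65445540 and CYP1A1 on chromosome 15 at 74719542 to 74725528 (GRCh38, whole gene spans).

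**Figure D2:**
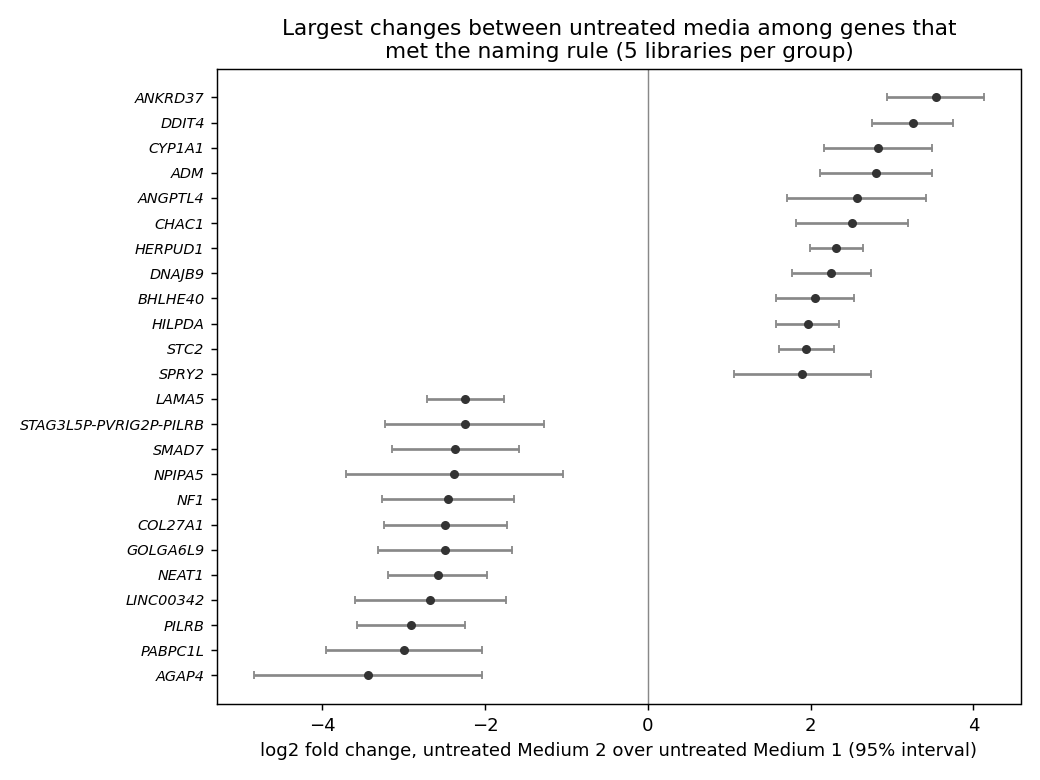
Points are log2 fold changes (x axis) of the 12 genes with the largest rise and the 12 with the largest fall between untreated Medium 2 and untreated Medium 1 (y axis, 5 libraries per group), with bars for 95% intervals. They were taken among genes that passed, averaged at least 10 CPM in the higher group, had a symbol not based on a clone and had libraries that did not overlap between the groups. They run from 3.53 for ANKRD37 to -3.44 for AGAP4.

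Some members of 3 stress-linked lists rose. In the list of the integrated stress response driven by the transcription factor ATF4, 12 of 28 measured members rose and 16 did not pass, and 14 rose when adjusted over the list alone (camera adjusted p = 3.09e-15, and 3.64e-05 with an estimated correlation). Its members DDIT3, which encodes the stress factor CHOP, ATF3 and the leucine sensor gene SESN2 rose by 1.74, 1.52 and 1.06, while asparagine synthetase ASNS had a log2 fold change of 0.13 (95% interval -0.37 to 0.64, adjusted p = 0.835). In the list of the unfolded protein response, 5 of 16 members rose and 11 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 3.38e-09, and 1.95e-05 with an estimated correlation). The 5 were HERPUD1, DNAJB9, the transcription factor XBP1 with 0.89, the chaperone HSPA5 with 0.70 and SDF2L1 with 0.68, the last a call lost without any 1 of the libraries in wells C1, D1, E1, G4 and H4 (adjusted p 0.0541 to 0.0786). Of 18 targets of p53, 5 rose and 13 did not pass, the same number as when adjusted over the list alone (camera adjusted p = 6.66e-05, and 0.00114 with an estimated correlation). These were the stress cytokine GDF15 with 1.59, BTG2 with 1.14, the cell death gene BBC3 with 0.70, the cell cycle inhibitor CDKN1A with 0.66 and the p53 ligase MDM2 with 0.62.

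Some early response and inflammatory genes were higher in Medium 2 as well. Among growth factor immediate early genes 12 of 27 rose and 15 did not pass, and 15 rose when adjusted over the list alone (camera adjusted p = 2.58e-15, and 0.00114 with an estimated correlation). EGR1, a transcription factor induced within minutes of a stimulus, rose from 92.6 ± 16.1 to 309 ± 56.3 CPM, a log2 fold change of 1.73 (SE 0.16, adjusted p = 3.56e-12), and the AP-1 subunits JUN and JUNB rose by 1.74 and 1.59. Interferon response genes rose in 8 of 17 cases, with 12 when adjusted over the list alone (camera adjusted p = 7.17e-12, and 0.000114 with an estimated correlation), among them the antiviral genes IFIT2 with 1.21, IFIT3 with 1.01, IFIT1 with 0.89 and the RNA sensor DDX58 with 0.65. Of 10 inflammatory genes driven by NF-kB, the 4 genes BIRC3 with 1.17, TNFAIP3 with 1.07, IER3 with 0.78 and NFKBIA with 0.43 rose, NFKBIZ fell by 0.95 and 5 did not pass. Adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 6.66e-05, and 0.014 with an estimated correlation). The NFKBIZ call was lost without any 1 of the untreated libraries in wells B1, E1, G4 and B5, with adjusted p-values from 0.0848 to 0.142.

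Some aryl hydrocarbon receptor targets differed between the untreated media before any exposure. CYP1A1, CYP1B1 with 1.62 and TIPARP, an inhibitor of that receptor, with 1.39 rose, and the other 8 of 11 members did not pass. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.000213, and 0.00458 with an estimated correlation). In the list of genes that respond to butyrate and inhibitors of histone deacetylases, ANGPTL4, CDKN1A and the metallothionein MT2A (0.36) rose and 12 of 15 did not pass, while 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.75e-05, and 0.000427 with an estimated correlation). Starvation targets of FOXO and MondoA held 3 members that rose, the cyclin CCNG2 with 1.72, the cell cycle inhibitor CDKN1B with 0.85 and KLHL24 with 0.77, which was lost without A1, B1, A5 or C5 (adjusted p 0.0504 to 0.101). The other 12 of 15 did not pass, and 4 rose when adjusted over the list alone (camera adjusted p = 0.000272, and 0.0334 with an estimated correlation). S-phase replication genes held 3 of 20 that rose, MCM2 with 0.67, CDC6 with 0.40 and RRM2 with 0.29, and when adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.00178, and 0.0254 with an estimated correlation). The CDC6 call was lost without C1, D1, G4 or A5 (adjusted p 0.0583 to 0.109).

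Another 5 lists passed camera with its preset correlation and not with an estimated one. Hypoxia response genes included ANKRD37, ADM, ANGPTL4, HILPDA and the angiogenic factor VEGFA with 1.44, all of which rose, and the demethylase KDM4B, which fell by 0.74. The other 13 of 19 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 8.56e-06, and adjusted p = 0.117 with an estimated correlation). The KDM4B call was lost without any 1 of 6 untreated libraries, in wells B1, D1, E1, G4, A5 and B5 (adjusted p 0.0677 to 0.148). Of 23 genes of glycolysis and glucose uptake, the glucose transporter SLC2A3 with 1.71 and the enzymes ALDOA with 0.67, GPI with 0.60 and PKM with 0.53 (adjusted p = 0.05, below the threshold before rounding) rose and 18 did not pass. The PKM call was lost without any 1 of 7 libraries, in wells A1, B1, C1, D1, E1, H4 and B5 (adjusted p 0.0601 to 0.192), and with RLE scaling, no filter, plate row or thinning (0.0531 to 0.145). PFKFB4 fell by 1.17, a call lost without the library in well E1 (adjusted p = 0.0971). Adjusted over the list alone, 7 rose and 1 fell (camera adjusted p = 0.000551, and adjusted p = 0.269 with an estimated correlation). Cytosolic ribosomal proteins rose in 20 of 79 cases, for example RPLP0 with 0.38 and RPL39 with 0.35, and in 41 when adjusted over the list alone (camera adjusted p = 1.33e-19, and adjusted p = 0.0712 with an estimated correlation). In the cholesterol list 2 members rose, among them MSMO1 with 0.38, 1 fell and 22 of 25 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.223 with an estimated correlation). The MSMO1 call was lost without the library in well B5 (adjusted p = 0.0521). Nuclear-encoded oxidative phosphorylation had 1 member of 31 that rose, ATP5G3 with 0.34, also when adjusted over the list alone (camera adjusted p = 0.0241, and adjusted p = 0.39 with an estimated correlation), and this call was lost without the library in well B1, E1 or B5 (adjusted p 0.0529 to 0.0874).

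For 12 lists camera did not pass between the untreated media. Adjusted p-values were 0.291 for aminoacyl-tRNA synthetases, 0.552 for fatty acid synthesis, 0.253 for autophagy and lysosome genes and 0.0762 for NRF2 oxidative stress targets. They were 0.449 for heme and iron handling, 0.761 for the kynurenine pathway, 0.499 for Wnt targets and colon stem cell genes and 0.0651 for colonic epithelial differentiation. The rest had 0.291 for mitosis, 0.528 for ribosome biogenesis, 0.452 for the heat shock response and 0.127 for the epithelial-mesenchymal transition. Within them the Wnt feedback genes RNF43 and AXIN2 fell by 1.27 and 1.05, and the mitotic genes CENPE, CENPF and MKI67 fell by 0.87, 0.58 and 0.48. Left-out libraries ended the calls of AXIN2 in 5 of 10 fits (wells C1, E1, G4, A5 and B5, adjusted p 0.0501 to 0.108), of CENPF in 7 (B1, C1, D1, E1, H4, B5 and C5, 0.0539 to 0.113) and of MKI67 in 8 (those 7 and A5, 0.0505 to 0.224). Without a filter on low counts the calls of AADAT, AXIN2, CDC6, CENPF, KDM4B, MKI67, NFKBIZ, RRM2 and SDF2L1 were lost (adjusted p 0.0541 to 0.0923). Thinning to equal depth ended those of AADAT, AXIN2, CENPF, KDM4B, MKI67, NFKBIZ and PFKFB4 (0.0575 to 0.196), a term for plate row those of KDM4B and NFKBIZ (0.0944 and 0.0898), and leaving out ribosomal RNA that of MKI67 (0.0509). In the kynurenine pathway the transaminase AADAT fell by 1.20, a call lost without any 1 of 8 untreated libraries, in wells A1, B1, C1, D1, G4, H4, A5 and C5 (adjusted p 0.0506 to 0.105), and that list's median was 0.039 against a mean of -0.162 and a downward test. The heat shock list had a median of -0.062, a mean of 0.066 and an upward test. The growth regulator MYC had a log2 fold change of 0.28 (95% interval -0.35 to 0.91, adjusted p = 0.699), and the cholesterol synthesis enzyme HMGCS1 had 0.14 (adjusted p = 0.543). Markers of fibroblasts, immune, endothelial and erythroid cells could hardly be tested, as 1 of them was measured, with a log2 fold change of -0.81 that did not pass, and 0 mRNAs encoded by the mitochondrial genome were in the tested set.

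Averaged over the 6 treatments, with 30 libraries in each medium, 2564 genes were higher and 2628 lower in Medium 2. HERPUD1 rose by 2.34 (SE 0.07, adjusted p = 4.28e-38), STC2 by 1.36 and CCNG2 by 1.39, and NEAT1 fell by 2.53 (SE 0.12, adjusted p = 3.09e-26). CCDC146 fell by 2.12, and GOLGA8B and NPIPB3, which share sequence with close copies, fell by 2.55 and 2.06. Of the ATF4 list 20 of 28 rose, also when adjusted over the list alone (camera adjusted p = 9.29e-12, and 0.000319 with an estimated correlation). Of cytosolic ribosomal proteins 74 of 79 rose, with 75 when adjusted over the list alone (camera adjusted p = 6.22e-24, and 0.0488 with an estimated correlation). Interferon response genes rose in 12 of 17 cases (camera adjusted p = 1.07e-08, and 0.000902 with an estimated correlation) and in 13 when adjusted over the list alone. In all 15 lists passed camera, each upward, and 9 of them also did with an estimated correlation. The media also lay in different parts of the plate, with the Medium 1 libraries in wells A1 to F4 by columns and the Medium 2 libraries in wells G4 to D8.

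Butyrate at 1 µM was compared with untreated spheroids in each medium. In Medium 1 the 1 gene that passed was ASNS, which makes asparagine, at 192 ± 107 CPM against 80.7 ± 27 (SD, n = 5), a log2 fold change of 1.24 (SE 0.24, adjusted p = 0.0482). Other ATF4 targets had smaller values that did not pass, such as 0.58 for the amino acid transporter SLC7A5 and 0.62 for ATF4 itself (adjusted p = 0.388 and 0.448). Over the ATF4 list 1 of 28 rose, and 10 rose when adjusted over the list alone (camera adjusted p = 1.68e-07, and 0.0115 with an estimated correlation). Ribosome biogenesis genes shifted upward with a median log2 fold change of 0.22 and 26 of 26 not passing singly (camera adjusted p = 0.000128, and 0.0287 with an estimated correlation). Interferon response genes shifted downward with a median of -0.30, and 3 of 17 fell when adjusted over the list alone (camera adjusted p = 7.42e-06, and 0.0174 with an estimated correlation). CDKN1A, a gene known to respond to butyrate at higher doses, had a log2 fold change of 0.10 (95% interval -0.14 to 0.34, adjusted p = 0.826). The ASNS call was lost without any 1 of 6 libraries, with an adjusted p of 0.917 without the butyrate library in well G1 and of at least 0.063 without those in wells B1, C1, D1, E1 and H1, while leaving out the one in well B2 gave 2 genes. It was also lost without a filter, with only the compared groups fitted, with a term for plate row and after thinning (adjusted p 0.102 to 0.609).

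In Medium 2 butyrate gave 0 genes by edgeR, 398 at an unadjusted p under 0.05 and 0 by DESeq2. Interferon response genes again shifted downward, with a median of -0.31 and 5 of 17 members that fell when adjusted over the list alone (camera adjusted p = 2.55e-12, and 0.000199 with an estimated correlation). IFIT1 was at 393 ± 66.5 CPM against 538 ± 34.5 in untreated spheroids, a log2 fold change of -0.46 (adjusted p = 0.791). CDKN1A had -0.28 (95% interval -0.53 to -0.04, adjusted p = 1). The response to butyrate differed between the media for 0 genes by edgeR and by DESeq2, with 482 at an unadjusted p under 0.05, and edgeR gave 1 without the Medium 2 butyrate library in well E5. The ATF4 list differed, lower in Medium 2 than in Medium 1 by a median of -0.43 with 28 of 28 members not passing singly (camera adjusted p = 5.28e-07, and 0.017 with an estimated correlation). Its members CHAC1 and TRIB3 had differences of -1.42 and -0.71 (adjusted p = 0.983 for both).

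Hemin at 0.1 µM was compared with untreated spheroids next. In Medium 1 the DNA repair factor SWI5 rose by 1.37 (SE 0.27, adjusted p = 0.0211), from 5.53 ± 2.11 to 14.3 ± 3.33 CPM (SD, n = 5). The cholesterol synthesis enzyme CYP51A1 fell by 0.58 (SE 0.11, adjusted p = 0.0211), from 262 ± 24.2 to 176 ± 30.4 CPM, and the phosphodiesterase PDE9A fell by 1.46 (SE 0.31, adjusted p = 0.0424), from 30.7 ± 8.46 to 11.1 ± 6.12 CPM. Heme oxygenase HMOX1, the enzyme that breaks down heme, was at 46.2 ± 10.2 CPM against 35.3 ± 6.57, a log2 fold change of 0.39 (SE 0.20, adjusted p = 0.235). The transferrin receptor TFRC had -0.36 (SE 0.11, adjusted p = 0.0651), the ferritin chain FTH1 -0.11 and ALAS1, the first enzyme of heme synthesis, -0.29 (adjusted p = 0.546 and 0.34). Camera passed for 0 of 27 lists, the heme and iron list included, against 3 by fry.

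The count for hemin in Medium 1 depended on the tool and on single libraries, with 2422 genes at an unadjusted p under 0.05, 3 past the adjusted threshold by edgeR and 569 by DESeq2. Leaving out the hemin library in well G2 gave 1190 genes, the untreated one in well B1 gave 159 and the hemin one in well E2 gave 43. Without the hemin library in well F2 the count was 1, and it was 0 without any 1 of the libraries in wells A1, C1, E1, C2 and D2. The call of SWI5 was lost in 5 of the 10 such fits (adjusted p 0.0633 to 0.2), that of CYP51A1 in 6 (0.0717 to 0.2) and that of PDE9A in 7 (0.0851 to 0.227), each among the libraries in wells A1, C1, D1, E1, C2, D2 and F2. All 3 were lost without a filter or after thinning (adjusted p 0.0513 to 0.0632), and CYP51A1 and PDE9A with a term for plate row (0.132).

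In Medium 2 hemin gave 0 genes by edgeR, 850 at an unadjusted p under 0.05 and 0 by DESeq2, while edgeR with only the compared groups gave 4, all lower. HMOX1 was at 46.2 ± 3.86 CPM against 48.7 ± 6.71, a log2 fold change of -0.08 (95% interval -0.48 to 0.32, adjusted p = 0.953), and TFRC had -0.06, FTH1 -0.01 and ALAS1 0.04. Interferon response genes shifted downward by a median of -0.26, and 1 of 17 fell when adjusted over the list alone (camera adjusted p = 1.23e-06, and 0.0146 with an estimated correlation). Growth factor immediate early genes had a median of -0.32 with the same camera p, which was 0.106 as an adjusted p with an estimated correlation. The response to hemin differed between the media for 0 genes by edgeR, with 1498 at an unadjusted p under 0.05, 9 by DESeq2 and 6 with only the compared groups, and without the Medium 1 hemin library in well G2 edgeR gave 99. It gave 1 without any 1 of the libraries in wells B1, C2, F2, H4, C5 and A6. EGR1 had the smallest p among named genes, with a difference of -1.14 (SE 0.23, adjusted p = 0.0543), and for HMOX1 the difference was -0.47 (95% interval -1.03 to 0.09).

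Kynurenine at 1 µM raised some targets of the aryl hydrocarbon receptor, a transcription factor that some tryptophan breakdown products activate. In Medium 1 CYP1A1 rose from 1.47 ± 1.05 to 7.55 ± 1.64 CPM (SD, n = 5), a log2 fold change of 2.31 (SE 0.34, adjusted p = 8.03e-05), and TIPARP from 37.4 ± 7.37 to 87.1 ± 15.1, a log2 fold change of 1.21 (SE 0.21, adjusted p = 0.00241). STC2 rose by 0.95 (SE 0.17, adjusted p = 0.00292) and INSIG2, which restrains cholesterol synthesis, by 0.96 (SE 0.20, adjusted p = 0.0369). CYP1B1 had 1.27 (SE 0.28, adjusted p = 0.0748) and AHRR, a repressor of the receptor, 0.02 (95% interval -0.71 to 0.75, adjusted p = 1). Of the 11 measured receptor targets 2 rose, and 4 when adjusted over the list alone (camera adjusted p = 5.9e-09, and 4.6e-05 with an estimated correlation). The hypoxia list shifted upward by a median of 0.36, with INSIG2 as the 1 of 19 that rose and 3 when adjusted over the list alone (camera adjusted p = 4.62e-14, and 0.0225 with an estimated correlation). The butyrate and histone deacetylase list had a median of 0.10 and 2 of 15 members that rose when adjusted over the list alone (camera adjusted p = 0.0129, and 0.0451 with an estimated correlation). The INSIG2 call was lost without any 1 of the libraries in wells A1, B1, C1, H2 and B3 (adjusted p 0.0879 to 0.462), and with only the compared groups, a term for plate row or thinning (0.067 to 0.184).

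In Medium 2, where CYP1A1 started higher, it rose with kynurenine from 10.9 ± 1.59 to 29.1 ± 7.78 CPM, a log2 fold change of 1.42 (SE 0.22, adjusted p = 0.000158). ALDH1A3, which makes retinoic acid, rose from 108 ± 12.5 to 257 ± 52.2 CPM, a log2 fold change of 1.25 (SE 0.16, adjusted p = 8.81e-07). IFIT1 fell by 0.52 (SE 0.11, adjusted p = 0.0458), from 538 ± 34.5 to 377 ± 44.6 CPM. TIPARP was at 65.1 ± 24.2 CPM against 98.4 ± 18.6, a log2 fold change of -0.59 (adjusted p = 0.563). CYP1B1 had 0.82 (SE 0.24, adjusted p = 0.34) and AHRR 0.79 (SE 0.31, adjusted p = 0.631). Receptor targets held 2 of 11 that rose, and 4 that rose and 1 that fell when adjusted over the list alone (camera adjusted p = 0.000367, and 0.0107 with an estimated correlation). Interferon response genes shifted downward by a median of -0.38, with 1 of 17 that fell and 4 when adjusted over the list alone (camera adjusted p = 3.66e-08, and 0.00378 with an estimated correlation). DESeq2 called 15 genes against 3, and leaving out the kynurenine library in well F6 gave 6. The IFIT1 call was lost without any 1 of 8 libraries, in wells G4, H4, A5, B5, C5, F6, H6 and B7 (adjusted p 0.0509 to 0.177), and with RLE scaling, no filter, only the compared groups, plate row or thinning (0.0631 to 0.593). With only the compared groups fitted the CYP1A1 call was lost as well, at a log2 fold change of 1.43 (adjusted p = 0.0588).

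The response to kynurenine itself differed between the media for 2 genes. The difference of log2 fold changes, Medium 2 minus Medium 1, was -1.80 for TIPARP (SE 0.30, adjusted p = 0.000991) and -1.57 for the Notch target HES1 (SE 0.32, adjusted p = 0.0327). For CYP1A1 it was -0.89 (95% interval -1.73 to -0.05, adjusted p = 1) and for INSIG2 -1.35 (adjusted p = 0.0727). Of 27 lists, 5 passed camera downward, led by hypoxia response genes with a median of -0.56 and immediate early genes with -0.46, and their adjusted p-values with an estimated correlation were 0.0882 and 0.0624. The HES1 call was lost without any 1 of 9 of the 20 libraries, in wells B1, D1, B3, D3, G4, A5, G6, H6 and A7 (adjusted p 0.0506 to 0.132), with only the compared groups (0.107) and without the 2 libraries that stood apart (0.0751). The count of 2 was 1 without those in wells B1, D1, B3, D3, G4, A5, H6 or A7, 4 without A3 or B5, 5 without C3 and 6 without F6.

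**Figure D3:**
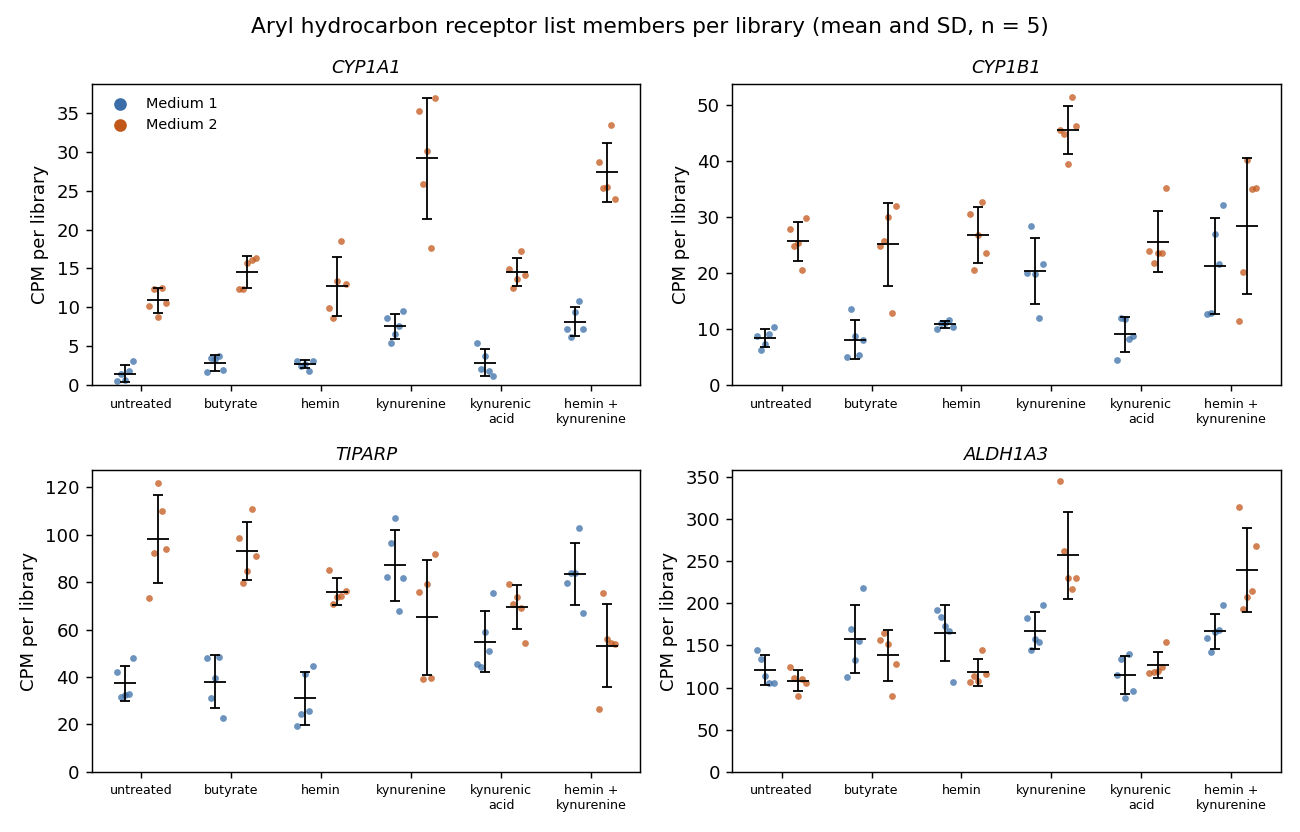
Points are CPM per library (y axis, linear) of CYP1A1, CYP1B1, TIPARP and ALDH1A3 for the 6 treatments (x axis) in Medium 1 and Medium 2, with lines for the mean and SD of 5 libraries. CYP1A1 averaged 7.55 CPM with kynurenine and 1.47 without treatment in Medium 1, and 29.1 and 10.9 CPM in Medium 2.

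Kynurenic acid, which cells form from kynurenine by transamination and ring closure, was given at the same 1 µM. Against untreated spheroids of Medium 1 it gave 0 genes by edgeR, 362 at an unadjusted p under 0.05 and 0 by DESeq2. CYP1A1 was at 2.86 ± 1.75 CPM against 1.47 ± 1.05, a log2 fold change of 0.93 (95% interval 0.13 to 1.74, adjusted p = 0.999), and TIPARP had 0.55, CYP1B1 0.11 and AHRR -0.42 (adjusted p = 0.999 for each). Camera passed for 4 lists, each downward, and for none with an estimated correlation, where ribosomal proteins and oxidative phosphorylation had an adjusted p of 0.666, and cholesterol and interferon genes of 0.402. In Medium 2 EGR1 fell by 0.80 (SE 0.16, adjusted p = 0.0343), from 309 ± 56.3 to 178 ± 11.2 CPM, and the selenium transport protein gene SEPP1 fell by 1.53 (SE 0.31, adjusted p = 0.0343). CYP1A1 had 0.41 (adjusted p = 0.687), TIPARP -0.50 (adjusted p = 0.511), AHRR -0.16 and CYP1B1 0.00. Mitosis genes shifted upward by a median of 0.19 with 1 of 20 rising when adjusted over the list alone (camera adjusted p = 9.89e-06, and 0.00184 with an estimated correlation), as with AURKA at 0.40 and TOP2A at 0.32 (adjusted p = 0.278 and 0.45). Wnt targets and colon stem cell genes shifted downward by a median of -0.33, with 2 of 15 that fell when adjusted over the list alone (camera adjusted p = 0.00279, and 0.0122 with an estimated correlation). Both single calls depended on several libraries. EGR1 was lost without any 1 of the 7 in wells G4, A5, C7, D7, E7, F7 and G7 and SEPP1 also without that in well C5, with adjusted p-values from 0.0521 to 0.311, so that each of the first 7 fits gave 0 genes and the fit without C5 gave 1. Thinning ended both (0.0541 and 0.0737), and SEPP1 was also lost without a filter, with only the compared groups and with plate row (0.0726 to 0.121).

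The response to kynurenic acid differed between the media for 0 genes by edgeR and by DESeq2, with 521 at an unadjusted p under 0.05, and for 1 with only the compared groups or plate row. EGR1 had a difference of -1.05 (SE 0.23, adjusted p = 0.248) and TIPARP of -1.05 (SE 0.30, adjusted p = 0.924).

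At the matched dose of 1 µM, kynurenic acid was then set directly against kynurenine. In Medium 1 CRYM, which encodes a thyroid hormone binding protein, was lower with kynurenic acid by a log2 difference of -1.24 (SE 0.25, adjusted p = 0.0236), at 6.94 ± 0.877 against 16.6 ± 1.4 CPM. STC2 differed by -0.85 (SE 0.17) and the glycolytic regulator PFKFB4 by -1.44 (SE 0.29), both with an adjusted p of 0.0236. CYP1A1 differed by -1.38 (95% interval -1.99 to -0.77, adjusted p = 0.0596) and CYP1B1 by -1.17 (95% interval -1.73 to -0.60, adjusted p = 0.139). Over the 11 receptor targets the median difference was -0.25, and 4 were lower when adjusted over the list alone (camera adjusted p = 1.01e-06, and 0.000868 with an estimated correlation). Hypoxia response genes were lower by a median of -0.50, with 7 of 19 lower when adjusted over the list alone (camera adjusted p = 1.01e-12, and 0.036 with an estimated correlation), and FOXO and MondoA targets by -0.31 (camera adjusted p = 6.13e-05, and 0.0472 with an estimated correlation). The count of 3 fell to 0 without any 1 of the libraries in wells H2, B3, D3, F3, G3 and A4 and to 1 without A3 or E3, and adjusted p-values of these genes were then between 0.0532 and 0.217. CRYM was lost without C3 too. Thinning ended all 3 calls (0.0679 to 0.236), only the compared groups those of CRYM and STC2 (0.0612 for both), and no filter that of CRYM (0.0651).

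In Medium 2 ALDH1A3 was lower with kynurenic acid, at 127 ± 15.2 CPM against 257 ± 52.2 with kynurenine, a log2 difference of -1.01 (95% interval -1.33 to -0.70, adjusted p = 0.000242). CYP1A1 differed by -1.01 (95% interval -1.44 to -0.57, adjusted p = 0.0987), while TIPARP had 0.08 (95% interval -0.34 to 0.50, adjusted p = 0.981), an interval that leaves room for a difference either way. Receptor targets differed by a median of -0.21, with 1 of 11 lower and 4 when adjusted over the list alone (camera adjusted p = 0.00103, and 0.0205 with an estimated correlation). Heat shock genes were higher with kynurenic acid by a median of 0.26, with 1 of 11 when adjusted over the list alone (camera adjusted p = 0.00177, and 0.0297 with an estimated correlation), for example HSPA8 at 0.32 (adjusted p = 0.48). Leaving out any 1 of the libraries in wells F6, A7 and F7 gave 2 genes in place of 1, and DESeq2 gave 3.

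The combination of hemin and kynurenine was compared with untreated spheroids in each medium. In Medium 1 CYP1A1 rose from 1.47 ± 1.05 to 8.14 ± 1.88 CPM (SD, n = 5), a log2 fold change of 2.41 (SE 0.34, adjusted p = 1.53e-05). TIPARP rose by 1.15 (SE 0.21, adjusted p = 0.00642) and CYP1B1 by 1.35 (SE 0.28, adjusted p = 0.0382), from 8.36 ± 1.54 to 21.2 ± 8.6 CPM. These were the 3 genes that passed, and receptor targets held 4 of 11 that rose when adjusted over the list alone (camera adjusted p = 8.4e-12, and 2.45e-06 with an estimated correlation). HMOX1 had 0.22 (95% interval -0.18 to 0.62, adjusted p = 0.951), AHRR 0.50, TFRC -0.26, ALAS1 0.04 and FTH1 0.03. Ribosomal proteins had a median of -0.16 with 79 of 79 not passing singly (camera adjusted p = 3.23e-15, and adjusted p = 0.288 with an estimated correlation). The TIPARP call was lost without the untreated library in well B1 or the combination library in well E4 (adjusted p 0.0564 to 0.0612), which left 1 gene each. CYP1B1 was lost without any 1 of 8, in wells A1, B1, C1, D1, E1, D4, E4 and F4 (0.0679 to 0.83), with only the compared groups (0.196) and with plate row (0.176).

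In Medium 2 the combination changed 63 genes, 35 upward and 28 downward. CYP1A1 rose from 10.9 ± 1.59 to 27.4 ± 3.81 CPM, a log2 fold change of 1.33 (SE 0.22, adjusted p = 0.000256), and ALDH1A3 from 108 ± 12.5 to 240 ± 50.3 CPM, a log2 fold change of 1.15 (SE 0.16, adjusted p = 9.26e-06). The dynein light chain DYNLL2 rose by 1.03 and COMMD5 by 0.84. The developmental transcription factor SOX9 fell by 0.81 (SE 0.15, adjusted p = 0.00124), HES1 by 1.27 (SE 0.23, adjusted p = 0.000721), EGR1 by 1.00 (SE 0.16, adjusted p = 0.000128), IFIT2 by 0.90 (SE 0.15, adjusted p = 0.000187) and the vesicle protein SYT1 by 0.98 (SE 0.17, adjusted p = 0.000489). These 9 genes passed in each of the 10 fits that left out 1 of the compared libraries. TIPARP fell by 0.88 (SE 0.20, adjusted p = 0.0271) and DDIT4 by 1.03 (SE 0.22, adjusted p = 0.0117). HMOX1 had 0.11 (95% interval -0.27 to 0.50, adjusted p = 0.83), CYP1B1 0.14 (adjusted p = 0.829), AHRR 0.09, FTH1 0.08, TFRC -0.09 and ALAS1 -0.41 (adjusted p = 0.263).

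The other named genes of that comparison passed more narrowly. Upward were SURF2 with 1.13, the small nucleolar RNA host SNHG12 with 1.06, RP9 with 0.96, CCDC34 with 0.87, the tubulin TUBA4A with 0.84, the centriole gene POC1A with 0.80, PNISR with 0.76, the proteasome subunit PSMB1 with 0.76, the chaperone HSP90AA1 with 0.38 and the ribonucleotide reductase subunit RRM2 with 0.36. Downward were RGS5 by 1.29, SGK223 by 0.98, ANKRD37 by 0.96, TANC2 by 0.86, BHLHE40 by 0.85, the plasminogen activator PLAT by 0.76, SOX4 by 0.48 and IFIT3 by 0.47. Each of these was lost in at least 2 of the 10 fits without 1 library, HSP90AA1 in all 10, as was DDIT4 without A5 or H7 and TIPARP without A5, B5, H7 or D8, with adjusted p-values of at most 0.23. Without a filter on low counts all of these but TUBA4A, PNISR and DDIT4 were lost (0.0585 to 0.131). Other settings ended calls of HSP90AA1, BHLHE40, CCDC34, IFIT3, PLAT, POC1A, RGS5, RRM2, SGK223, SNHG12 and TANC2 (0.0513 to 0.222). The count of 63 itself was 36, 24, 17, 38 and 22 without the untreated libraries in wells G4, H4, A5, B5 and C5, and 15, 30 and 26 without the combination libraries in wells H7, A8 and D8. DESeq2 gave 134.

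Of the lists in that comparison, growth factor immediate early genes shifted downward by a median of -0.50, with EGR1 as the 1 of 27 that fell and 10 when adjusted over the list alone (camera adjusted p = 9.54e-08, and 0.0452 with an estimated correlation). Interferon response genes held 2 of 17 that fell, IFIT2 and IFIT3, and 7 when adjusted over the list alone (camera adjusted p = 1.17e-07, and 0.00734 with an estimated correlation). Wnt targets and colon stem cell genes held 2 of 15 that fell, SOX9 and SOX4, also when adjusted over the list alone (camera adjusted p = 0.00632, and 0.0267 with an estimated correlation). Mitosis genes shifted upward by a median of 0.17 and 2 of 20 rose when adjusted over the list alone (camera adjusted p = 0.00204, and 0.0267 with an estimated correlation). S-phase genes shifted upward by 0.14, with RRM2 as the 1 of 20 that rose and 3 when adjusted over the list alone (camera adjusted p = 0.00343, and 0.0468 with an estimated correlation). The combination libraries of Medium 2 were also deeper, with 2585791 ± 299786 counts against 1804067 ± 156723 (exact permutation p = 0.00794, the smallest that 5 against 5 libraries can give, and 0.0873 after adjustment over 11 comparisons). They had 14181 ± 147 detected genes against 13732 ± 177 (exact permutation p = 0.00794, adjusted 0.0437).

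**Figure D4:**
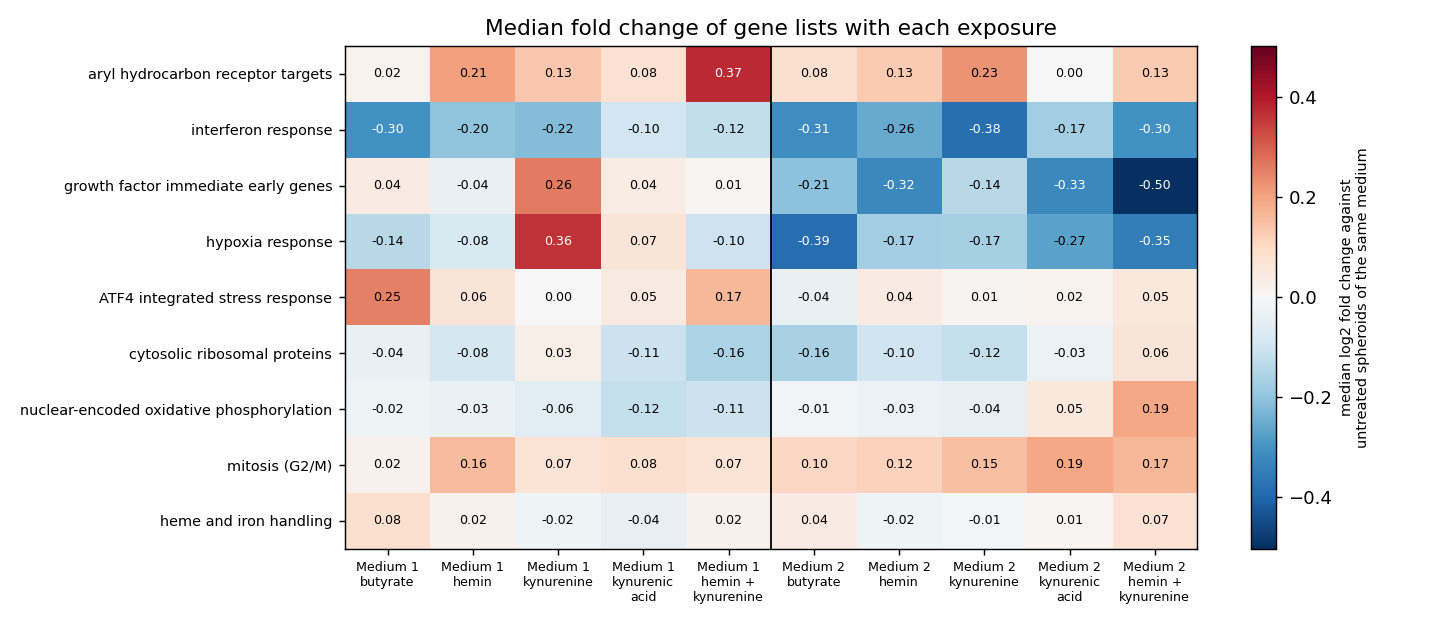
Cells give the median log2 fold change of the measured members of 9 gene lists (y axis) for each exposure against untreated spheroids of its own medium (x axis, 5 libraries per group), with red for positive and blue for negative values. Aryl hydrocarbon receptor targets have 0.37 with the combination in Medium 1, and growth factor immediate early genes have -0.50 with the combination in Medium 2.

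The response to the combination differed between the media for 3 genes. The difference, Medium 2 minus Medium 1, was -2.03 for TIPARP (SE 0.29, adjusted p = 3.99e-05), -1.35 for EGR1 (SE 0.23, adjusted p = 0.000891) and -1.06 for SOX9 (SE 0.21, adjusted p = 0.0118), the last with an adjusted p of 0.0555 without the Medium 2 combination library in well H7. CYP1A1 had a difference of -1.08 (95% interval -1.91 to -0.25, adjusted p = 0.462) and ALDH1A3 of 0.68 (adjusted p = 0.361). Camera passed for 6 lists, among them oxidative phosphorylation with a median difference of 0.30 and immediate early genes with -0.34, and both had an adjusted p of 0.134 with an estimated correlation. The count of 3 was 5 without the library in well A1 or B5 and 6 without that in well C4, and DESeq2 gave 18.

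Whether the combination differed from the sum of its parts was asked with the log2 fold change of the combination minus those of hemin and of kynurenine alone. This takes the doses in the combination to be those of the single exposures, while the titles of the combination give 1 µM after kynurenine and no separate dose of hemin. In Medium 1 this gave 0 genes by edgeR and by DESeq2, with 955 at an unadjusted p under 0.05, and in Medium 2 it gave 0 by edgeR, 1410 at an unadjusted p under 0.05 and 42 by DESeq2. For CYP1A1 the departure was -0.74 (95% interval -1.69 to 0.20, adjusted p = 0.654) in Medium 1 and -0.33 (95% interval -0.97 to 0.30, adjusted p = 0.707) in Medium 2. INSIG2 had -1.36 in Medium 1 (SE 0.29, adjusted p = 0.139), and IFIT1 had 0.49 in Medium 2 (SE 0.15, adjusted p = 0.195). Camera passed for 4 and 5 lists, and for none with an estimated correlation. Leaving out the Medium 2 kynurenine library in well F6 gave 132 genes in Medium 2, and the count was 1 without that in well D6, E6, B7, H7 or C8, as in Medium 1 without the untreated library in well E1.

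Some measures of the libraries moved with the groups. Untreated Medium 2 had 13732 ± 177 detected genes against 14193 ± 187 in untreated Medium 1 (SD, n = 5, exact permutation p = 0.00794, the smallest possible, and 0.0437 adjusted over 11 comparisons) at similar totals of 1804067 ± 156723 and 1831599 ± 228724 (exact permutation p = 0.984). Mitochondrial ribosomal RNA made up 1.75% ± 0.0607 of counts against 1.62% ± 0.0816 (exact permutation p = 0.0238, adjusted 0.262). Hemin libraries of Medium 2 were shallower, with 1552197 ± 188501 counts (exact permutation p = 0.0397, adjusted 0.218).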

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

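The 3 patterns weighed here were chosen after the results were seen, and so were the tests with thinned counts, of the library in well H7 and of gene lists in untreated against exposed libraries.

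Within groups of 5 libraries, a library was singled out where its gap to the nearest other library was more than 0.71 of the range of the group, which chance gives in about 1 in 20 groups. Library totals and the other measures of the libraries had 0 such gaps in 48 cases, and examined genes had 29 in 346, of which the untreated Medium 1 library in well A1 held 6. In untreated Medium 1 the highest CPM stood apart for ATF4 at 408 in well B1 (others 300 to 325), BIRC3 at 28.7 in E1 (23.5 to 24.9), EGR1 at 121 in B1 (81.3 to 89.6), HMGCS1 at 601 in A1 (444 to 489), JUN at 39.5 in E1 (27.2 to 30.8), MSMO1 at 312 in A1 (at most 269) and SLC7A5 at 205 in A1 (136 to 145). The lowest stood apart there for P4HA1 at 69.7, MKI67 at 263 and PKM at 528 in A1 (155 to 184, 314 to 330 and 637 to 681), DDX58 at 60.5 in C1 (74.6 to 78.7), PILRB at 15.7 in D1 (22.4 to 25.1) and SARS at 59.3 in D1 (69.7 to 74). In untreated Medium 2 they were RP9 at 43.4 in G4 (23.6 to 27.7) and RPLP0 at 2818 in B5 (2400 to 2509), both highest, and PNISR at 128 in A5 (148 to 157) and SLC2A3 at 7.26 in B5 (11.5 to 13), both lowest. With butyrate in Medium 1 the library in well G1 was highest for ASNS at 374 (92.2 to 174) and CARS at 356 (176 to 212), and it was 1 of 6 libraries whose removal ended the ASNS call of that comparison, with an adjusted p of 0.917 (edgeR). PDE9A stood at 21.8 in the hemin library of well G2 (6.11 to 9.61) and IFIT1 at 292 in the combination library of well E4 (207 to 219), both in Medium 1. In Medium 2 ANKRD37 was lowest at 35.3 in the butyrate library of well H5 (89.8 to 112) and at 71.3 in the hemin library of well D6 (99.3 to 109), and IFIT2 at 61.6 in the combination library of well H7 (120 to 135). With kynurenic acid in Medium 2 the gaps were AHRR at 4.59 in D7 (7.85 to 9.04), lowest, and ALDH1A3 at 154, CYP1B1 at 35.1 and TOP2A at 584 in G7 (117 to 125, 21.7 to 23.9 and 398 to 452) and TNFAIP3 at 17.3 in F7 (6.53 to 9.55), highest.

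Responses that differed between the media by the interaction test of edgeR were those of TIPARP and HES1 to kynurenine, by -1.80 and -1.57 on the log2 scale, and those of TIPARP, EGR1 and SOX9 to the combination, by -2.03, -1.35 and -1.06. TIPARP started higher in Medium 2, at 98.4 ± 18.6 CPM without treatment against 37.4 ± 7.37 in Medium 1 (SD, n = 5).

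A first pattern is the set of 416 genes that were lower in untreated Medium 2, with a median log2 fold change of -0.894, of which 33 of the 410 with a known class (8.05%) are not protein-coding, against 3.67% of 10374 genes that were not called and 1.32% of the 304 higher genes (Fisher's exact p = 4.85e-05, lower against all others, odds ratio 2.34). Removing the trend of fold change on gene span, fitted over all genes, left 95.5% of the median (bootstrap 95% interval 92.3 to 99). This argues only against a smooth effect of length, shared by all genes, as the whole cause. Median spans were 46.3 kb for the lower genes, 31.2 kb for those not called and 16.8 kb for the higher ones. A part played by length thus stays open. A lower recovery of nuclear RNA cannot be told apart from other causes. The median of 33 small nuclear and nucleolar RNAs was 0.477 (0.338 to 0.676) where the test set in advance needed -0.449 or less, but such RNAs are poor markers in libraries primed on poly(A), and 39 nuclear-retained transcripts had a median of -0.149, below random lists (-0.0179 to 0.146). A gradual change over the plate is argued against by the Medium 1 group nearest to the Medium 2 wells. It lay 6.81% of the way to untreated Medium 2 (1.54 to 11.9). A step between the wells of the 2 media cannot be told apart from the medium itself. A response of the cells to the medium, which may include the hours without nutrients that the design names, stays open and untested, as does any handling that differed between the media.

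A second pattern is that interferon response genes had a negative median log2 fold change with each of the 5 exposures in both media, from -0.379 to -0.173 in Medium 2 and from -0.304 to -0.096 in Medium 1. These comparisons share their untreated libraries. The mean log2 CPM of the 17 genes was lower in the 25 exposed than in the 5 untreated libraries by 0.32 in Medium 2 (25 of 25 exposed libraries below the untreated mean) and by 0.20 in Medium 1 (24 of 25). Because the list was picked for such values, a test on it alone was set aside. In its place the difference was set, in each of 142506 assignments, against the largest standardized difference of any of the 27 lists. This argues against chance values of the untreated libraries as the whole cause in Medium 2 (permutation p = 9.82e-05) and only narrowly in Medium 1 (permutation p = 0.0365), with each medium taken alone. Mean covariance of the Medium 2 fold changes over all genes was 0.0405, against 0.0299 to 0.0331 in 100 simulations without effects. The excess was 0.00904 (Medium 1 0.00715), and split untreated libraries gave 0.0108. In Medium 2 the correlation was not in excess (0.5 against 0.503), so shared untreated libraries cannot be excluded as the whole source. This says nothing about the list. In Medium 2 the median over exposures of the members measured after thinning was -0.305 then and -0.304 before. Thinning keeps the expected share of each gene in a library, so this cannot decide whether depth played a part. A response common to all exposures may account for the pattern, and so could a feature shared by the untreated libraries of each medium, which lie side by side in wells A1 to E1 and G4 to C5, and these cannot be separated here.

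The last pattern is the 63 genes called for the combination in Medium 2, against 3 for kynurenine and 0 for hemin (edgeR, with 850 at an unadjusted p under 0.05 and 0 by DESeq2). More calls through greater depth alone are argued against, since 54 genes were called after thinning, 41 of them shared with the 63. Whether the count rests on the library in well H7 cannot be told apart from other causes, because the count was 15 without it and was also at most 38 without any 1 of 7 others (17 without A5, 22 without C5, 24 without H4, 26 without D8, 30 without A8, 36 without G4 and 38 without B5). The departure from the sum of both exposures alone was called for 0 genes by edgeR, with 1410 at an unadjusted p under 0.05, and 42 by DESeq2, so a stronger response to the combination stays a hypothesis.

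Each count of genes was also set against 100 assignments of the same libraries to groups of the same sizes, the real one included. The shares below were not adjusted over the 21 contrasts, and 1 of 100 is the smallest share possible. Chance can be excluded for the 720 genes between untreated media (1 of 100 as large, highest other 37) and the 5192 averaged over treatments (1 of 100, highest other 97). It can be excluded for kynurenine and the combination in Medium 1 with 4 and 3 genes (1 of 100 and highest other 1 for each), and for the combination in Medium 2 with 63 (1 of 100, highest other 1). The same holds for the difference between media with the combination (3 genes, 1 of 100, highest other 0) and for kynurenic acid against kynurenine in Medium 1 (3 genes, 1 of 100, highest other 0). For kynurenic acid in Medium 2 chance is excluded only narrowly, with 2 called genes (1 of 100, highest other 1). That count was 0 without any 1 of 7 libraries and after thinning. The difference between media with kynurenine also had 2 called genes (1 of 100, highest other 1). By the number at an unadjusted p under 0.05, assignments as large were 63 of 100 for the difference with kynurenine, 12 and 13 for kynurenine and the combination in Medium 1 and 32 for kynurenic acid against kynurenine in Medium 1, so that chance cannot be excluded there by that measure. For the 3 genes of hemin in Medium 1, 4 of 100 assignments were as large, a share not adjusted over the 21 contrasts. The highest other, 719 genes, came from exchanging the hemin library in well G2 with the untreated one in B1. An exchange of G2 with A1 gave 428, which points to a structure of these libraries that the groups do not follow. The count was also 0 without a filter and after thinning, so chance is not taken as excluded here. Chance cannot be excluded for the 1 gene of butyrate in Medium 1 (5 of 100, highest other 10), the 3 of kynurenine in Medium 2 (5 of 100, highest other 130, with A7, G6 and H6 beside 2 untreated libraries) and the 1 of kynurenic acid against kynurenine in Medium 2 (12 of 100, highest other 8), and these higher counts point to structure of the samples too. This concerns the counts and not the single genes ALDH1A3 and CYP1A1 with kynurenine and ALDH1A3 between the 2 compounds, which passed in each of the 10 fits without 1 library.

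Where edgeR called 0 genes, the number at an unadjusted p under 0.05 was compared in the same way. Chance can be excluded for hemin in Medium 2 (850 genes, 2 of 100 as large, highest other 1029, DESeq2 0), for its difference between media (1498, 2 of 100, highest other 1544, DESeq2 9) and for the departure from additivity in Medium 2 (1410, 4 of 100, highest other 2159, DESeq2 42), by that measure alone. For the departure from additivity, other assignments called up to 197 and 74 genes past the adjusted threshold where the real one called 0. This points to structure of the samples, so the low unadjusted share does not show a departure. Chance cannot be excluded either for kynurenic acid in Medium 1 (362, 39 of 100, highest other 822), butyrate in Medium 2 (398, 21 of 100, highest other 659), the departure from additivity in Medium 1 (955, 7 of 100, highest other 1517), or the differences between media with butyrate (482, 50 of 100, highest other 1697) and kynurenic acid (521, 20 of 100, highest other 1001). DESeq2 called 0 genes in these 5. The 1697 genes of 1 assignment again point to structure of the samples.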

How the results depend on the processing

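The plate row term, leaving out ribosomal RNA, thinning to equal depth and leaving out 2 libraries that stood apart were chosen after the data were seen. No paired analysis was possible because the columns of the table carry no replicate number, so the replicate block for counts and for camera was not run. Of 160 calls of single genes examined, 107 kept their direction and stayed past the threshold under every alternative run and 0 reversed. Calls were lost for 0 of the 150 to which DESeq2 gave an adjusted p, 3 with RLE scaling, 35 without a filter, 13 with only the compared groups, 19 with plate row, 2 without ribosomal RNA, 27 after thinning, 1 without the 2 libraries, and 51 without some 1 library. Over all values of these and other examined genes under alternatives, called or not, 11562 stayed on their side of the threshold, 399 kept their direction and no longer passed, 74 newly passed and 55 that were not called moved. Of 139 list calls by camera, 43 stayed past the threshold with an estimated correlation and 69 with fry. No alternative moved the median log2 fold change of all genes between untreated media beyond 0.0178. For the counts below the cause was not tested. In simulations at the real depths 35.8% of genes changed 1.5-fold, drawn from those of at least 10 CPM, were recovered. This does not separate depth from the number of libraries or their spread.

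With only the compared groups fitted, untreated media gave 1135 genes in place of 720. In Medium 1, butyrate gave 0 in place of 1 without a filter, with only the compared groups, with plate row and after thinning, and 3 without the 2 libraries. Hemin gave 569 by DESeq2, 17 with RLE scaling, 0 without a filter, 225 with only the compared groups, 1 with plate row, 17 without ribosomal RNA, 0 after thinning and 759 without the 2 libraries, in place of 3. Kynurenine gave 7 in place of 4 with only the compared groups and without the 2 libraries. In Medium 2, hemin gave 4 in place of 0 with only the compared groups. Kynurenine gave 15 by DESeq2 and 1 with only the compared groups in place of 3. Kynurenic acid gave 1 without a filter and with plate row and 0 after thinning in place of 2. The combination gave 134 by DESeq2, 22 without a filter and 117 without the 2 libraries in place of 63.

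The difference between media gave, for hemin in place of 0, 9 by DESeq2, 6 with only the compared groups and 1 with each other alternative (RLE scaling, no filter, plate row, no ribosomal RNA, thinning and without the 2 libraries). For kynurenine it gave 1 with only the compared groups and without the 2 libraries and 5 with plate row in place of 2. For kynurenic acid it gave 1 with only the compared groups and with plate row in place of 0. For the combination it gave 18 by DESeq2, 6 with only the compared groups and without the 2 libraries and 5 with plate row in place of 3. The departure from additivity in Medium 2 gave 42 by DESeq2 in place of 0. Kynurenic acid against kynurenine in Medium 1 gave 1 with only the compared groups, 0 after thinning and 7 without the 2 libraries in place of 3. In Medium 2 it gave 3 by DESeq2 and without the 2 libraries, and 2 with plate row and after thinning, in place of 1.

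Leaving out each library in turn gave 528 to 594 genes between untreated media and 5083 to 5413 averaged over treatments. In Medium 1 it gave 0 to 2 for butyrate, 0 to 1190 for hemin, 3 to 6 for kynurenine and 1 to 3 for the combination. In Medium 2 it gave 2 to 6 for kynurenine, 0 to 3 for kynurenic acid and 15 to 61 for the combination. For the difference between media it gave 0 to 1 for butyrate, 0 to 99 for hemin, 1 to 6 for kynurenine and 2 to 6 for the combination, and for the departure from additivity 0 to 1 in Medium 1 and 0 to 132 in Medium 2. Kynurenic acid against kynurenine gave 0 to 4 in Medium 1 and 1 to 2 in Medium 2. Most of the single libraries behind these ranges are named with each comparison. Others were B5 and C5 for 528 and 594 between untreated media, A8 and A7 for 5083 and 5413 averaged, C3 for 6 with kynurenine in Medium 1, B5 for 3 with kynurenic acid and C8 for 61 with the combination in Medium 2, and H3 for 4 with kynurenic acid against kynurenine in Medium 1. By edgeR it gave 0 in each such fit for butyrate and hemin in Medium 2, kynurenic acid in Medium 1 and its difference between media.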

Other observations

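The tests in this part were chosen after other results had been seen, while the list of nuclear-retained transcripts and its prediction were written before that list was tested.

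Untreated spheroids of Medium 2 were also set against the mean of the 5 exposed groups of that medium. HES1 was higher without exposure by 1.00 (SE 0.16, adjusted p = 0.000561), IFIT2 by 0.65 (SE 0.11, adjusted p = 0.000561), EGR1 by 0.63, SEPP1 by 0.99, DDIT4 by 0.74, SOX4 by 0.42 and IFIT1 by 0.38, and COMMD5 and ALDH1A3 had differences of -0.64 and -0.63, with adjusted p-values of at most 0.0281 in edgeR's quasi-likelihood test. Calls of these genes thus need not be specific to 1 exposure. In Medium 1 edgeR gave 0 such genes, with 917 at an unadjusted p under 0.05, and DESeq2 was not run. Each other group against the mean of the rest of its medium gave 145 genes for the combination in Medium 2, 114 for hemin, 7 for kynurenine, 3 for the combination and 1 for butyrate in Medium 1, and 2 for kynurenine in Medium 2. It gave 0 for kynurenic acid in Medium 1 and for butyrate, hemin and kynurenic acid in Medium 2, with 617, 591, 976 and 547 at an unadjusted p under 0.05.

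NEAT1 and other long noncoding or readthrough RNAs stood among the largest falls in Medium 2, which led to the hypothesis that retention of unspliced or nuclear RNA differs between the media. It was tested on 39 measured transcripts known for retained introns or nuclear retention, of 44 listed, with genes already seen among the largest changes left out. Averaged over treatments their median log2 fold change was -0.132, below the central 95% of 10000 random lists matched on expression (-0.0111 to 0.163), of which 0 had a median as low. Of the 39, 19 fell, among them ZNF692 by 1.75 and the glycosyltransferase gene OGT by 0.93, and 8 rose, among them the splicing kinases CLK1 with 1.31 and CLK4 with 1.29. Between untreated groups the median was -0.149 (random lists -0.0179 to 0.146), with 7 that fell and 3 that rose. The result is consistent with the hypothesis for part of the list, but 3'-end counts do not tell spliced from unspliced RNA, so a change in transcription or decay of the same genes may give these values too.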
